A study of Homo sapiens with 4 samples.

How the data were processed

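RNA of Y79 cells grown for 5 days with or without a polymeric scaffold was hybridised to 4 Agilent whole human genome arrays (design 014850), 2 per group. Per the labels' protocols, 500 ng of total RNA was primed with oligo-dT, amplified and labelled with Cy3, so each array has 1 colour. Per the file headers, the deposited intensity values came from Agilent Feature Extraction 10.5.1.1, which subtracts background, removes spatial trends and puts a surrogate where a spot does not exceed background, without normalization between arrays. The deposited files also give the mean intensity and the local background intensity of each spot, and 0 or 1 flags for signal well above background, saturation and outliers. The authors deposited a table of log2 ratios as well, and how it was made is not given in the sources used here. Set against the scanner files, its log2 ratios lay within 0.02 of the difference between same-marked arrays after 75th percentile scaling for 99.9% and 99.8% of probes, and its 2 control columns were 0 throughout.

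The main values were log2 processed signals minus each array's 75th percentile over non-control spots. Spots marked as non-uniform or population outliers were left out (117 to 171 per array), saturated spots were kept, and spots of 1 probe were averaged. A probe entered if it was well above background on at least 2 of the 4 arrays, and each gene name was represented by its probe with the highest mean over the 4 arrays. Other probes of a gene can disagree, and the report says where a probe well above background on all 4 arrays and unsaturated had the opposite sign or under 0.5 times the log2 fold change of the one used. A probe not well above background on both arrays of a group has only a bound, taken as the bright group's mean against, per array, the higher of the probe's own signal and the lowest signal well above background. No fold is given where both groups were saturated. A gene counts as measured in one group alone only if none of its probes was well above background on any array of the other group. Signal over background limits the dim genes: the lowest signal well above background was 28.8 to 50.5 over the arrays, against a 75th percentile of 876 to 1479.

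Gene names in the files are those of the array's design. Of the 41000 probes, 23950 were named through their accession in a RefSeq table of assembly GRCh38.p14, 2763 had a current symbol, 1032 were named through a unique synonym, and 13255 kept the file's name. That table was used for names only, and coordinates are those of the files in hg18, for the 60-base probe's own place. A symbol that is part of a read-through locus kept the symbol in the file, and 14 of 969 list memberships were carried to a current symbol, both decided after seeing the data. No genome sequence was used here, so whether a probe lies in an exon or UTR is not given.

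Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), with Benjamini-Hochberg adjustment over all gene names and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 1.28. Gene lists fixed before the data were examined, 52 in all, were tested with camera at its preset correlation of 0.01 where at least 5 members were measured, and again with an estimated correlation and with fry. The named genes also followed a rule fixed before the data were examined. Among genes with a symbol, well above background and unsaturated on all 4 arrays, with groups that did not overlap and an adjusted p under 0.05, the 12 largest rises and 12 largest falls were named. Up to 4 called members with the largest change were eligible per list, with RB1, MYCN, CRX, GAPDH, MKI67, COL1A1 and FN1 always, the 5 largest bounds per direction and the 5 genes at each end of the authors' table. Not every eligible list member is printed, and those printed were picked after their values were seen.

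The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, a 75th percentile over probes well above background on all arrays, no filter, a filter on all 4 arrays, the mean over a gene's probes, each probe tested on its own, eBayes with trend and robust variance, arrays with the word replicate in their title as a block, and leaving out each array in turn. Cyclic loess, scaling to the spike-ins and leaving out saturated probes were added after seeing the data. The steps were tested on simulated data with the same 24403 gene names and the same spread, with 200 genes changed in the comparison of scaffold with no scaffold. At a log2 change of 0.5 the fit called 2 of 50, at 1 it called 28 of 50, at 2 it called 44 of 50 and at 4 it called 48 of 50, and 4 of 24203 unchanged genes were called. In the data 16630 gene names passed, which loosens the Benjamini-Hochberg cutoff, so these shares do not give the sensitivity there. In the simulation, where genes varied independently of each other, a list lowered by 1 was called with the preset correlation, as was 1 other list. With an estimated correlation the adjusted p of the lowered list was 0.166. Figures were drawn with matplotlib 3.10.9.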

Results

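Gene expression was measured in Y79 cells, an established human retinoblastoma line that grows in suspension, after 5 days of culture with or without a polymeric scaffold. The series holds 4 single-colour Agilent arrays, 2 of cells grown with the scaffold and 2 of cells grown without it. Nothing in the labels says whether the 2 arrays of a group came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. All 4 arrays lay on 1 slide with 1 scan time, so neither splits the samples, and their number limits the precision of every value. Each array carried 43376 non-control spots for 41000 probes. The arrays with scaffold were dimmer: the 75th percentile of the processed signal was 916 and 876 with scaffold and 1479 and 1404 without. The share of spots well above background was 76.2% and 71.7% with scaffold, and 79.1% and 83.3% without. Levels are log2 signals relative to each array's 75th percentile, given as mean ± SD over the 2 arrays of a group, and folds compare the group means.

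The comparison asked which transcripts differ between cells grown with and without the scaffold. Cells with scaffold had far higher transcripts of SAG (arrestin, which shuts off activated rhodopsin) and GUCA1A (a calcium sensor that regulates retinal guanylate cyclase). They had far lower transcripts of BEX3, the neurofilament subunit NEFM (with the brighter of its probes only) and the homeobox genes LHX2 and OTP. Of the measured rod and pan-photoreceptor genes 19 of 25 rose, most genes of cholesterol synthesis fell and most genes of amino acid supply rose. Camera called these lists with its preset correlation, but not with an estimated one (adjusted p = 0.737). With an estimated correlation camera also missed a list lowered by 1 in simulated data (adjusted p = 0.166), so the missing calls do not decide. The simulated genes varied independently, so the simulation does not test the preset correlation either. Of 24403 gene names tested with limma, 16630 passed an adjusted p of 0.05, 10991 of them higher and 5639 lower with scaffold. The fitted difference was at least 2-fold in 3473, with 2070 higher and 1403 lower, and some of these have only a bound. This majority turned with the scaling, as the next paragraph shows. Among gene names well above background and unsaturated on all 4 arrays, 1875 were at least 2-fold higher and 935 lower, and at 16-fold or more 4 were higher and 15 lower. The 2 groups did not overlap for 88.4% of gene names, against 33.3% by chance. At an unadjusted p under 0.05 the count was 17712. Without the second array of cells grown without scaffold, 10750 gene names passed, and without the first of them 11753.

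The share of higher calls depended on the scaling. It was 66.1% with the 75th percentile, 58.0% after median centring, 54.5% after quantile normalization and 53.3% after cyclic loess, and with spike-in scaling it was 15.8%. Among differences of at least 2-fold the share was 59.6% with the 75th percentile, 48.6% with that of probes well above background, 43.0% after median centring, 43.1% after quantile normalization, 39.9% after cyclic loess and 9.35% with spike-in scaling. Of genes measured on all 4 arrays, 1172 were at least 2-fold higher and 1229 lower after cyclic loess, and 419 higher and 3715 lower with spike-in scaling, while at 16-fold lower genes outnumbered higher ones under all 6 scalings. The median log2 fold change over all genes was 0.30 with the 75th percentile, 0.21 with that of probes well above background and 0.16 after median centring. It was 0.10 after quantile normalization, 0.10 after cyclic loess and -0.33 with spike-in scaling. Small differences of either sign are to be read against that offset. With spike-in scaling every log2 fold change is lower by the difference between 0.30 and -0.33, and rises smaller than that turn to falls there. Across arrays, 8 labelled spike-in transcripts that were measurable on all 4 arrays differed by a median of -0.05 in unscaled log2 signal, with a range of -0.27 to 0.18, while the 75th percentile of the genes differed by -0.69. After the 75th percentile scaling the same spike-ins stood 0.64 higher with scaffold. An exact two-sided permutation test of 2 against 2 arrays cannot give a p under 0.333. Replicate arrays correlated across genes at r = 0.991 with scaffold and 0.996 without, against 0.952 to 0.956 between groups, where genes are not independent replicates.

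The 2 largest rises among genes measured on all arrays were of photoreceptor transcripts. SAG stood at 1.94 ± 0.04 with scaffold and -2.70 ± 0.02 without (SD, n = 2 arrays each), a 25.0-fold rise (log2 4.64, SE 0.04, adjusted p = 0.00118). Its probe lies on chromosome 2 at 233920358 to 233920417 in hg18, the build of the array's annotation. GUCA1A, with its probe on chromosome 6 at 42254519 to 42254578, rose 20.2-fold from -3.77 ± 0.01 to 0.56 ± 0.04. CPLX3, a complexin of ribbon synapses, rose 17.1-fold, from 0.86 ± 0.03 to 4.95 ± 0.00, with its probe on chromosome 15 at 72910549 to 72910608. Of 25 measured rod and pan-photoreceptor genes, 19 rose, 3 fell and 3 did not pass the test, with a median log2 fold change of 1.06. The adjusted p of each list here and below is that of camera. GNAT1, the rod transducin alpha subunit, rose by 3.17 on the log2 scale and NRL, the transcription factor that specifies rods, rose 7.65-fold, to 5.07 ± 0.10. The list was called higher by camera (adjusted p = 0.0210), a call that was lost with adjusted p = 0.737 with an estimated correlation. CRX, a transcription factor of rods and cones, rose 1.84-fold, from 0.19 ± 0.01 to 1.07 ± 0.00 (adjusted p = 0.00141). Among 14 cone photoreceptor genes, 9 rose and 1 fell, including GNGT2 (3.56-fold higher) and GNAT2 (3.53-fold higher), both subunits of cone transducin, and THRB, a thyroid hormone receptor of cone development, was 3.12-fold lower. The cone list was not called by camera (adjusted p = 0.147).

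The other large rises had no shared list. L1TD1, an RNA-binding protein of embryonic stem cells, rose 18.5-fold, with its probe on chromosome 1 at 62449712 to 62449771. FUOM, which interconverts fucose anomers, rose from -2.60 ± 0.02 to 1.40 ± 0.05 (1.97 higher in log2 with its other probe), and FUT1, a fucosyltransferase, rose 11.7-fold. TFF1, a secreted trefoil peptide, rose 11.9-fold, from -0.40 ± 0.04 to 3.17 ± 0.03, and its second probe was 2.72 higher on the log2 scale. NAV2 rose 12.9-fold with its brightest probe, but 2 dimmer probes that were well above background on all arrays differed much less, one by 0.40 in log2 and the other by just over 2-fold. GLI3, a transcription factor of Hedgehog signalling, rose 12.4-fold, HOXB9 11.5-fold, FBXO2 11.4-fold and SIGIRR, a negative regulator of interleukin-1 receptors, 11.2-fold. The adjusted p of these 9 genes was 0.00118 except for NAV2 at 0.00168.

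**Figure D1:**
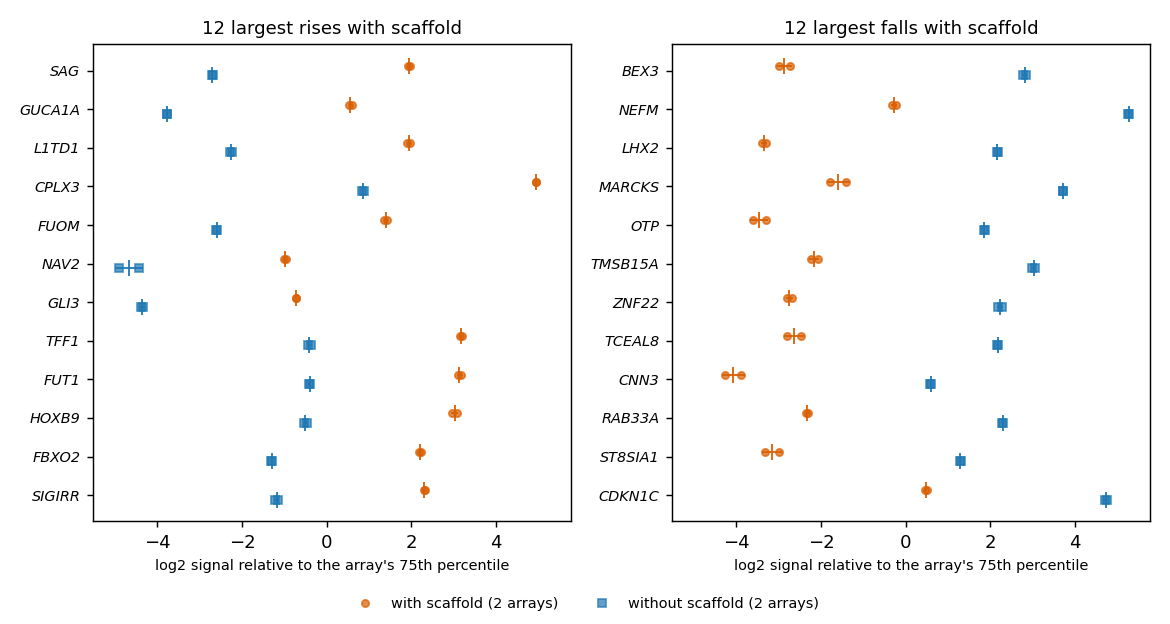
Levels of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) among genes measured on all arrays. The horizontal axis is the log2 signal relative to the array's 75th percentile, circles and squares are single arrays with and without scaffold, and ticks with bars are the mean ± SD of 2 arrays. The arrays of a group lie close together in each row, as for SAG at 1.94 ± 0.04 against -2.70 ± 0.02.

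The largest falls had no shared list. BEX3, a small signalling protein abundant in brain, fell 51.0-fold from 2.81 ± 0.06 to -2.87 ± 0.18 (log2 -5.67, SE 0.11, adjusted p = 0.00123), with its probe on chromosome X at 102519564 to 102519623. NEFM, the medium neurofilament subunit, fell 46.4-fold from 5.26 ± 0.00 to -0.27 ± 0.08, with its probe on chromosome 8 at 24831089 to 24831148. A dimmer NEFM probe, well above background on all arrays, showed no such fall, at -0.01 in log2. LHX2, a homeobox gene needed for eye formation, fell 45.5-fold from 2.16 ± 0.02 to -3.35 ± 0.08, and OTP, a homeobox gene of the hypothalamus, fell 39.6-fold. MARCKS, an actin-binding substrate of protein kinase C, was 39.8-fold lower, TMSB15A, a thymosin that binds actin monomers, 36.2-fold lower, and CNN3, an actin-binding calponin, 25.4-fold lower. The remaining large falls were ZNF22 at 31.6-fold, TCEAL8 at 28.0-fold, RAB33A at 24.4-fold, the ganglioside synthase ST8SIA1 at 21.9-fold and CDKN1C at 19.1-fold.

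The lists of other neurons, glia and pigment epithelium held strong changes in both directions. None was called by camera, whereas fry, described with the totals over all lists, called each of these 5. Of 16 genes of other retinal neurons, 7 rose and 3 fell: NEFL, the light neurofilament subunit, fell 14.1-fold with its brighter probe (-6.44 in log2 with the other) and CABP5, a calcium-binding protein of bipolar cells, rose 4.78-fold (list adjusted p = 0.777). This list had a positive median of 0.35 and a negative mean of -0.23. Among 17 neuroendocrine and synaptic genes, 7 rose and 7 fell, with INSM1, a transcription factor of neuroendocrine cells, 15.1-fold lower with its brighter probe (-1.27 in log2 with the other) and the synaptic calcium sensor SYT1 4.24-fold lower (adjusted p = 0.375). Its median was 0.06 and its mean -0.34. Of 13 retinal progenitor genes, 3 rose and 4 fell, among them LHX2 and ATOH7, which was 2.37-fold lower (-0.62 in log2 with its other probe), while PAX6 was 1.71-fold higher (adjusted p = 0.595). Of 12 genes of Mueller glia and astrocytes, 7 rose and 3 fell, with clusterin (CLU) 3.76-fold higher and CD9 2.20-fold lower (adjusted p = 0.777). Of 11 genes of retinal pigment epithelium and melanocytes, 4 rose and 3 fell, with DCT, an enzyme of melanin synthesis, 4.61-fold lower (adjusted p = 0.777).

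The leukocyte, fibroblast, endothelial and epithelial lists had median levels from -3.72 to -1.96, and most of their genes that passed the test were higher with scaffold. With spike-in scaling this turned in part, to 2 higher and 1 lower in both the leukocyte and the fibroblast list, none higher and 2 lower in the endothelial list, and 1 higher and 6 lower in the epithelial list. Dim genes rose in general with the main scaling: in deciles 1 to 3 of the level, 67.5% to 80.2% of calls were higher. After that scaling the lowest signal well above background stood at -4.33 with scaffold and -5.33 without, as means of 2 arrays. Rises of about 2-fold in these dim lists cannot be told apart from that shift. In the leukocyte list, 7 of 11 measured genes rose and none fell. CD79A, part of the B cell receptor, rose 3.52-fold (list adjusted p = 0.250). In the fibroblast list, 5 of 7 rose, with COL1A1 2.25-fold and THY1 2.08-fold higher (adjusted p = 0.296), and in the endothelial list 5 of 7 rose, with ERG 2.68-fold higher (adjusted p = 0.521). Among 9 epithelial genes, 4 rose and 2 fell, with KRT7 2.26-fold higher and KRT17 lower, well above background on 2 arrays (adjusted p = 0.697).

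Genes of cholesterol synthesis and uptake were lower with scaffold. Of 19 measured, 16 fell, 2 rose and 1 did not pass the test (17 fell when adjusted over the list alone), and the median log2 fold change was -0.55. MSMO1 and IDI1, enzymes of the sterol pathway, fell 3.64-fold and 3.56-fold. HMGCS1, which makes the precursor of mevalonate, fell 3.05-fold from 1.75 ± 0.01 to 0.14 ± 0.07. The list was called lower by camera (adjusted p = 1.34e-06), a call lost with adjusted p = 0.737 with an estimated correlation. Fatty acid synthesis and storage genes were split, 6 higher and 8 lower of 16 (adjusted p = 0.305). SREBF1, a master regulator of lipid synthesis, was 2.14-fold higher and DGAT1, which makes triglycerides, 2.21-fold higher. ELOVL6, a fatty acid elongase, was not well above background with scaffold and at least 14.4-fold lower there.

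Integrated stress response and amino acid supply genes were higher with scaffold. Of 20 measured, 19 rose and 1 fell, with a median log2 fold change of 1.26. TRIB3, a pseudokinase induced by ATF4, rose 5.29-fold from 3.29 ± 0.02 to 5.70 ± 0.01. CHAC1, a glutathione-degrading enzyme, rose 3.12-fold, CEBPB 3.01-fold and PHGDH, the first enzyme of serine synthesis, by 1.59 on the log2 scale. The list was called higher (adjusted p = 0.000982), again with adjusted p = 0.737 with an estimated correlation. In the unfolded protein response list, 8 genes rose and 5 fell of 19, with HERPUD1 2.32-fold higher and PDIA6 1.66-fold lower (adjusted p = 0.777). Heat shock genes gave 7 higher and 3 lower of 13, with DNAJB1 2.16-fold higher and HSP90AB1 1.85-fold lower (adjusted p = 0.903, median 0.22 and mean -0.13). Of 18 oxidative stress genes, 11 rose and 1 fell, with the cystine transporter SLC7A11 2.68-fold higher and TXNRD1 -0.89 in log2 (adjusted p = 0.444). Of 9 metallothioneins, 6 rose, led by MT1F at 2.43-fold (adjusted p = 0.329), and MT1G, MT3 and MT1A turned to falls with spike-in scaling.

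**Figure D2:**
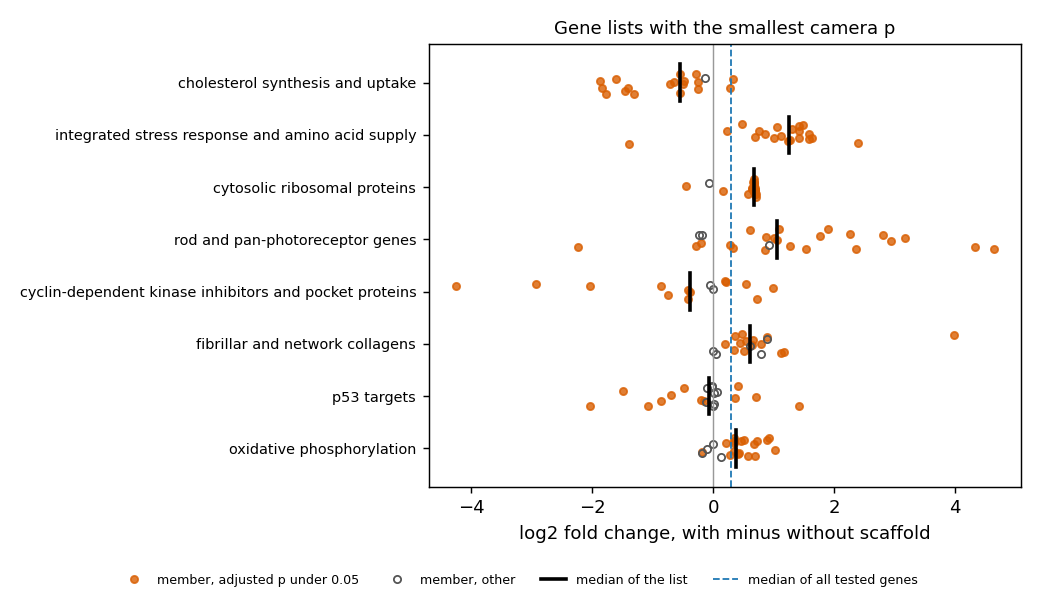
Members of the 8 gene lists with the smallest camera p. The horizontal axis is the log2 fold change, with minus without scaffold, each point is 1 gene, filled where its adjusted p was under 0.05, black bars are list medians and the dashed line is the median of all tested genes at 0.30. The median of the cholesterol list lies at -0.55 and that of the integrated stress response list at 1.26.

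Cytosolic ribosomal protein genes were called higher (adjusted p = 0.00621, but adjusted p = 0.737 with an estimated correlation), with 23 of 25 higher and 1 lower and a median of 0.68, but 21 of the 25 were saturated on all 4 arrays and so have no measured fold. A saturated signal is near the scanner's ceiling on every array, and the 75th percentile of the genes was 0.69 lower with scaffold, so the scaling alone sets it about that much higher. Without saturated probes 12 members remained and the list was not called (adjusted p = 0.667), with its median -0.25 relative to all genes. MYCN, the oncogene amplified in Y79 cells, was saturated on all 4 arrays with its brightest probe. Its dimmer probe stood 1.27 higher with scaffold on the log2 scale. RB1 was 1.16-fold higher with its brighter probe (adjusted p = 0.0262) but -0.42 in log2 with spike-in scaling, its call was lost under 11 of 16 alternatives, and its other probe differed by 0.05. GAPDH was saturated on 2 arrays, so the size of its difference was not measured. It was called higher (adjusted p = 0.0192), and its sign turned with quantile normalization at -0.26, cyclic loess at -0.22 and spike-in scaling at -0.36.

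The balance of the cell cycle genes depended on the scaling. Of 28 genes of G2/M and mitosis, 10 rose and 11 fell (5 and 15 after quantile normalization, 5 and 17 after cyclic loess, 1 and 22 with spike-in scaling, and the list was called lower with normexp at adjusted p = 0.00457 but not with an estimated correlation at 0.737), with CDCA3 2.14-fold and BIRC5 1.84-fold higher and NUSAP1 1.93-fold lower (adjusted p = 0.311). MKI67, a marker of dividing cells, was 1.52-fold lower (adjusted p = 0.00416). Of 29 S phase and DNA replication genes, 10 rose and 11 fell, with the ribonucleotide reductase subunits RRM2 and RRM1 2.47-fold and 1.79-fold lower, although a dimmer probe of RRM2 was 0.77 higher on the log2 scale (adjusted p = 0.424, median 0.04 and mean -0.02). Replication-dependent histones gave 8 higher and 2 lower of 11, with H2BC5 2.71-fold higher (0.35 in log2 with its other probe) and H1-2 2.23-fold lower (adjusted p = 0.424). Of 15 cyclin-dependent kinase inhibitors and pocket protein genes, 5 rose and 8 fell. CDKN1C fell 19.1-fold, CDKN2C 7.63-fold and CDKN1A 4.08-fold, whereas CDKN1B rose 1.98-fold, and the list fell short of the threshold (adjusted p = 0.0786). Of 20 p53 targets, 4 rose and 8 fell, with SESN2 2.68-fold higher and ZMAT3 2.82-fold lower (adjusted p = 0.0871). The p53 list was called lower under 4 of 17 alternatives, with adjusted p from 0.0041 with normexp to 0.737 with an estimated correlation. Apoptosis regulators were split, 8 higher and 9 lower of 19, with BIK 2.98-fold higher and PMAIP1 3.06-fold lower (adjusted p = 0.521).

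Matrix and adhesion genes are of interest because a scaffold offers a surface. Of 19 collagens, 14 rose and none fell, and the list fell short of the threshold (adjusted p = 0.0858). The list was dim, with a median level of -2.76, and dim genes rose in general with the main scaling. Its median log2 fold change was 0.62, and random lists of genes of like level had a median of 0.35. The collagens lay at the 94.6th percentile of those random lists, so the count alone does not set them apart. COL2A1, a cartilage and vitreous collagen, stood at -1.24 ± 0.02 with scaffold and -5.23 ± 0.12 without, where only 1 of the 2 arrays was well above background. COL18A1 rose 2.19-fold. FN1, the fibronectin gene, did not pass the test, at -5.63 ± 0.41 with scaffold and -4.87 ± 0.07 without (adjusted p = 0.0574), and was well above background on only 2 of the 4 arrays. It passed as lower under 7 of 15 alternatives, with a smallest adjusted p of 0.00278 with spike-in scaling, and was 0.62 higher in log2 with normexp, where it did not pass. Extracellular glycoproteins and proteoglycans were split, 7 higher and 5 lower of 19, with EFEMP1, a fibulin, 8.09-fold lower and VTN 1.02 higher in log2 (adjusted p = 0.834). Laminins gave 6 higher and 2 lower of 11, with LAMA3 3.08-fold lower and LAMC1 0.67 higher in log2 (adjusted p = 0.547). Of 20 integrin and focal adhesion genes, 7 rose and 8 fell, with ITGB4 3.04-fold higher and filamin A (FLNA) 2.33-fold lower (adjusted p = 0.424, median 0.18 and mean -0.15). Of 21 matrix proteases and inhibitors, 9 rose and 6 fell, and the metalloprotease inhibitors TIMP3 and TIMP1 rose 5.98-fold and 5.63-fold while the protease CTSL was -1.31 in log2 (adjusted p = 0.697). Collagen-modifying genes gave 7 higher and 4 lower of 14, with the lysyl hydroxylase PLOD1 3.74-fold higher and SERPINH1 -1.15 in log2 (adjusted p = 0.903). Cadherins and cell-cell adhesion genes gave 10 higher and 2 lower of 17, with N-cadherin (CDH2) 1.89-fold lower and VCAM1 1.87-fold higher (adjusted p = 0.700). Of 11 mesenchymal transition genes, 5 rose and 4 fell, with TGFBI 8.35-fold higher and S100A4 2.47-fold higher and ZEB2 lower, at -4.44 ± 0.16 with scaffold, where only 1 of the 2 arrays was well above background, and -2.02 ± 0.01 without (adjusted p = 0.777). Cytoskeleton and motility genes gave 8 higher and 10 lower of 19, with TPM2 2.58-fold higher and fascin (FSCN1) 2.48-fold lower (adjusted p = 0.266).

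Signalling lists were not called by camera, whereas fry called those of this paragraph except the immediate early genes. Of 17 Notch pathway genes, 9 rose and 4 fell, with the receptor NOTCH2 5.81-fold higher and MFNG, which glycosylates Notch receptors, 3.46-fold higher (adjusted p = 0.547). Of 19 Wnt pathway genes, 8 rose and 4 fell. WNT3A was measured with scaffold and not well above background without, at least 3.39 higher on the log2 scale, and AXIN2, a feedback inhibitor of the pathway, was 2.15-fold lower with its brightest probe and 0.19 higher on the log2 scale with another (adjusted p = 0.777). TGF-beta and BMP genes gave 7 higher and 8 lower of 20, with TGFB2 3.95-fold lower and BMP7 0.87 higher in log2 (adjusted p = 0.341, median 0.09 and mean -0.08). Of 19 receptor tyrosine kinase and growth factor genes, 13 rose and 3 fell, with IGFBP2 2.77-fold higher and IGF2 3.33-fold lower (adjusted p = 0.481). Hippo targets gave 6 higher and 2 lower of 10, with AJUBA 2.29-fold higher and AMOTL1 -0.80 in log2 (adjusted p = 0.718). Angiogenesis genes gave 11 higher and 2 lower of 19, with HGF 2.15-fold higher and FGF2 lower, well above background on 3 arrays (adjusted p = 0.266). Immediate early genes gave 9 higher and 6 lower of 18, with JUN 2.16-fold higher and KLF6 2.24-fold lower (adjusted p = 0.777).

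Immune and interferon genes also moved without a list called by camera, whereas fry called these 3 lists. Of 16 interferon response genes, 10 rose and 2 fell, with IFITM1 4.81-fold higher (adjusted p = 0.317). Of 12 antigen presentation genes, 4 rose and 5 fell, with the class I genes HLA-C 10.1-fold, HLA-B 4.95-fold and HLA-E 4.23-fold lower. Some dimmer probes measured on all arrays fell less, by -0.74 and -1.13 in log2 for HLA-C and -0.44 for HLA-B. One was 0.35 higher for HLA-E. A further HLA-C probe, at 0.67 and 0.70 without scaffold, was not well above background with it, and so was lower too. TAP1, a peptide transporter of the same list, was higher, at -1.68 ± 0.02 with scaffold and -4.84 ± 0.27 without, where only 1 of the 2 arrays was well above background (list adjusted p = 0.444, median 0.28 and mean -0.22). Of 12 NF-kappaB and cytokine genes, 7 rose and 1 fell, with RELB 1.87-fold higher and IRF1 lower, well above background on 2 arrays (adjusted p = 0.341).

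In metabolism, 17 of 22 oxidative phosphorylation genes rose and 1 fell, with COX6C 2.03-fold and NDUFB3 1.90-fold higher (adjusted p = 0.0871). The counts were 8 higher and 3 lower after quantile normalization, and 6 and 0 with normexp. The median log2 fold change of this list was 0.39, and random lists of genes of like level had 0.37, so it did not stand out from them. Glycolysis genes gave 9 higher and 5 lower of 18, which turned to 3 and 9 after quantile normalization, 4 and 6 after median centring, 5 and 9 after cyclic loess and 0 and 13 with spike-in scaling, with the lactate transporter SLC16A3 1.66-fold higher and PKM 1.63-fold lower (adjusted p = 0.986). Of 24 hypoxia response genes, 10 rose and 10 fell, with STC2 5.68-fold higher and MXI1 2.32-fold lower (adjusted p = 0.521). Autophagy and lysosome genes gave 7 higher and 9 lower of 22, with NPC1 3.45-fold lower and NPC2 3.06-fold higher, both transporters of cholesterol out of lysosomes (adjusted p = 0.311). Spliceosome and RNA processing genes gave 7 higher and 3 lower of 17, with SRSF3 1.57-fold higher and SNRPB -0.63 in log2 (adjusted p = 0.986). Of 17 multidrug transport and detoxification genes, 7 rose and 5 fell, with GSTM1 3.67-fold higher and the drug exporter ABCC4 2.05-fold higher (adjusted p = 0.848). Stem cell markers gave 9 higher and 3 lower of 15, with NES 2.49-fold higher and SALL4 3.80-fold lower (adjusted p = 0.697). Of 17 retinoblastoma tumour genes, 4 rose and 7 fell, with TFF1 11.9-fold higher and the kinase SYK 6.49-fold lower (adjusted p = 0.296).

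Over the 52 lists, camera called 4, with 3 higher and 1 lower, and none with an estimated correlation. That setting did not call a list lowered by 1 in simulated data either, so it cannot decide against the 4 calls. The simulated genes varied independently, so the simulation does not test the preset correlation of 0.01, which also called 1 other list there. In the data the estimated correlation was 0.050 for cholesterol, 0.091 for stress response, 0.627 for ribosomal protein and -0.0021 for rod and pan-photoreceptor genes. The counts of higher and lower genes given for the lists hold for the 75th percentile scaling: 36 lists had more higher than lower genes there, 32 after median centring, 27 after quantile normalization, 26 after cyclic loess and 6 with spike-in scaling. After quantile normalization and cyclic loess the excess of higher genes turned to lower in the glycoprotein, glycolysis, immediate early, unfolded protein response, heat shock and spliceosome lists. Fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, called 45 of the 52, 32 higher and 13 lower. When p-values were adjusted over the list alone, 674 memberships were called in place of 662, and no list changed by more than 2 members. Camera sets a list against all other genes, so its direction can differ from the sign of the median. Median and mean also differed in sign for G2/M and mitosis (-0.02 and 0.0015), retinal progenitors (0.16 and -0.45) and pigment epithelium (0.63 and -0.0057), besides the lists whose median and mean are given above. Relative to all genes, the median and the direction of the test differed in sign for matrix proteases, other retinal neurons, mesenchymal transition, pigment epithelium, immediate early and spliceosome genes.

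Some genes were measured in one group alone, which gives only a bound on their fold. Both arrays with scaffold but neither without measured 29 genes, and the reverse held for 1006 genes, of which 123 differed by at least 2-fold. HOXD3, a homeobox gene, was at least 18.6-fold higher with scaffold, MYRIP at least 7.38-fold, the potassium channel KCNJ5 at least 6.05-fold and IGFBP7 at least 5.46-fold, with WNT3A at least 3.39 higher on the log2 scale. RELN, the secreted guidance protein reelin, was at least 25.5-fold lower with scaffold, PHYHIPL at least 20.1-fold, TRO at least 16.9-fold, QRFPR at least 14.6-fold and ELOVL6 at least 14.4-fold. When a probe was instead required to exceed the 99th percentile of the negative controls, the counts became 0 with scaffold and 2707 without. That percentile was 38.4 and 124 on the arrays with scaffold and 19.6 and 20.2 without. By the flag, the lowest scaled signal well above background was also higher with scaffold, at -4.33 against -5.33. The cutoffs were thus unequal, and neither pair of counts gives the number of genes expressed in one group alone.

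The authors' deposited table gives 2 log2 ratios per probe, each of an array with scaffold over the array without that bears the same mark. In the authors' deposited table, HOXB3 had the highest mean of the 2 ratios among named genes, at 5.69 and 4.85, followed by SAG at 4.66 and 4.62, MYRIP at 4.09 and 4.64, HOXD3 at 4.12 and 4.58 and GUCA1A at 4.32 and 4.34. The lowest in the authors' deposited table were PHYHIPL at -6.79 and -6.32, NEFL at -6.37 and -6.52, RELN at -6.72 and -5.95, RND3 at -5.85 and -5.68 and CCDC85A at -5.62 and -5.80. For HOXB3, MYRIP, HOXD3, PHYHIPL, RELN, RND3 and CCDC85A the probe in question was not well above background in one group, so these ratios are not measured sizes. Both ratios of the authors' deposited table were at least 1 for 2391 probes and at most -1 for 1886, and for 250 probes they had opposite signs at that size.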

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

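All tests in this part were chosen after the data were seen, and no explanation was tested for them. A minimum size for the control probes was dropped after a first look at the values. Negative control spots, which match no human transcript, were well above background on 2 and 5 of 153 spots on the arrays with scaffold against 0 and 1 without, a signal outside the gene comparison. Among other control probes, which the comparison does not use, 3 were measured and brighter on both arrays with scaffold, although these arrays were dimmer as a whole. The unscaled log2 difference, with minus without scaffold, was 0.617 for AT_ssH_PC_3 (4 spots), 0.294 for AT_D_3 (10 spots) and 0.256 for AT_nD_3 (4 spots). Measured probes of the same series also went the other way, by more than the arrays as a whole: AT_ssH_TR_3 by -1.79, AT_ssH_TR_5 by -1.58, AT_ssH_RR_3 by -1.54 and AT_ssH_AB_5 by -1.23. What these probes match is not annotated in the files.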

How the results depend on the processing

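Cyclic loess, spike-in scaling and leaving out saturated probes were chosen after seeing the data, the other settings before. Of the values of single named genes under alternatives, 3386 kept direction and side of the threshold, 172 lost the call, 7 gained it and 21 reversed, the 7 gained all of FN1, and of the gene lists' values 861 were the same, 5 lost a call, 15 gained one and 2 reversed. Those that gained one were p53 targets (4 settings), collagens and cyclin-dependent kinase inhibitors (2 each), and G2/M, S phase, autophagy, cytoskeleton, oxidative phosphorylation, cone and interferon genes (1 each). The cause was not tested for any of the following unless stated. With normexp, 10872 gene names changed, 2724 of them lower, and 11 lists were called; SPARC (0.49), PARVA (0.19), DPPA4 (0.60), RPE65 (0.27), BEST1 (0.61), IRF1 (0.15) and FST (0.67) turned from lower to higher in log2, all of them well above background on only 2 of the 4 arrays. With quantile normalization GAPDH (-0.26) turned, and so did MYCN (-0.0013), whose probe was saturated on all 4 arrays, so its sign was not measured. The ribosomal protein list lay at -0.091 relative to all genes with that setting (adjusted p = 0.636). Averaging a gene's probes turned KRT14 (-0.29), H2BC21 (-0.81) and U2AF1 (-0.086). Another probe, unsaturated and well above background on all arrays, stood at -1.30 in log2 for H2BC21 and -1.03 for U2AF1. The U2AF1 probe used was saturated on all 4 arrays. Cyclic loess turned GAPDH (-0.22). With spike-in scaling 2186 gene names were higher and 11670 lower, and MT1G (-0.14), MT3 (-0.19), MT1A (-0.25), RB1 (-0.42) and GAPDH (-0.36) turned, since this setting lowers every scaffold value by about the same amount. Without saturated probes, which lets a dimmer probe stand for the gene, ALDOA (-0.66), HSPD1 (-0.21), HNRNPA1 (-0.46) and the ribosomal protein list (-0.25) turned. With an estimated correlation, which also missed the lowered list in simulated data, 0 gene lists were called, and the smallest adjusted p was 0.737. Fry called 45. With the 99th percentile of negative controls, which was higher on the arrays with scaffold, genes measured in one group alone numbered 2707 against 1035. Counting all such genes was chosen after the data were seen, and at 2-fold and more it gave 58 against 29 with and 123 without scaffold. Leaving out 1 array, with the lone array of its group assumed to vary like the other group, gave 10750 to 15624 changed, 7021 to 10354 higher and 3723 to 5270 lower; both low ends came from leaving out an array without scaffold (10750 and 11753 changed), and fewer arrays leave 1 residual degree of freedom. With the arrays marked replicate as a block, 14042 changed (9182 higher, 4860 lower, 3372 at least 2-fold) and 4 lists were called; the labels share only that word, and same-marked arrays' deviations correlated at -0.04 across genes. Signal over background limits dim genes: 1164 of the calls were not well above background on all arrays and 455 were saturated on at least 1.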

Other observations

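All tests in this part were chosen after the data were seen, and the gene families and members below were picked after their values were seen. Some families encoded side by side were lower with scaffold in most of their measured members. Of 13 measured protocadherin beta genes, cell surface proteins of neurons encoded in a row on chromosome 5, 10 were called lower with scaffold and none higher. PCDHB5 was 2.66-fold and PCDHB11 2.72-fold lower, measured on all arrays. Larger falls in the family were of genes well above background on only 2 arrays. The sequences of the family are alike, so a probe may also read a neighbour. It was lower with 11 to 12 of 13 called under the 5 other scalings. Of 13 BEX and TCEAL genes on chromosome X, 11 were lower, with BEX2 9.70-fold and BEX1 8.89-fold lower, and TCEAL7 was 1.77-fold higher, a call lost with spike-in scaling.

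HOX genes, which set position along the body axis and are not part of a retinal programme, moved both ways. Of 29 tested, 13 rose and 2 fell. Over all gene names 10991 of 24403 rose and 5639 fell, so the count of rises is close to the general share. The probe named HOXA10 lies on chromosome 12 at 52709820, near the HOXC6 probe, and did not pass the test. Among the HOX genes called, HOXB3, HOXD3 and HOXD8 (higher) and HOXC8 (lower) were well above background on only 2 arrays. HOXA3, at 6.23 with scaffold and 5.57 without, lay at the level of saturated probes, which the scaling alone sets higher. HOXB13 rose 6.74-fold and HOXD9 5.83-fold, while HOXC9 fell 9.31-fold. With cyclic loess 10 rose and 3 fell, and with spike-in scaling 7 rose and 4 fell. Of the neurofilament genes NEFL and NEFM fell (the dimmer NEFM probe showed -0.01 in log2) while NEFH was 1.72-fold higher, and NEFH was not called with spike-in scaling.

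The excess of higher calls is the first pattern weighed. After cyclic loess 53.3% of calls were higher, against 66.1% before, but that correction centres the arrays at each level whatever the cause, so it does not decide for brightness and scaling of the arrays as the source. The excess before loess lay at both ends of the signal range: by deciles of the level the median log2 fold change was 0.39 in the highest, 0.56 in decile 2 and 0.01 in decile 7. A true rise of most genes cannot be told apart from scaling, since the median of all genes was -0.33 with spike-in scaling and 0.10 with cyclic loess, and a difference in added spike-in would shift the former.

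The second pattern is the 19 differences of 16-fold and more among genes measured on all arrays, 15 of them lower. Dim arrays with scaffold cannot be judged by cyclic loess, after which 100% of the 19 stayed called and at least 8-fold. The 19 were picked as well above background on all arrays and at least 16-fold, which nearly fixed that outcome. The values do show that the largest median log2 fold change in any decile of the level was 0.56, far below 16-fold. Cells without high MYCN making up a whole group are argued against, since its brightest probe was saturated on 4 of 4 arrays. Only 1.37% to 1.86% of gene names were saturated there. A mixture stays open, and a first bound on the MYCN percentile was dropped after the result, since rank means nothing at the ceiling. Cells of another type in one group remain open: 0 of the 6 lists of such cells were called by camera, but every called gene of the leukocyte, fibroblast and endothelial lists was higher with the main scaling (not with spike-in scaling, where the endothelial list had 0 higher and 2 lower), and the bound for this test was tightened after its first result. The leukocyte, fibroblast and endothelial lists are dim. In deciles 1 to 3 of the level 67.5% to 80.2% of all calls were higher, so their rises do not single out cells of another type. The scaffold itself is the biological explanation the design names, and it stays untested against any other difference between the cultures.

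The third pattern, chosen for testing after a scan with smaller windows, is that neighbouring genes shifted together. Over windows of 50 adjacent genes, with each gene set against the median of genes of like signal level, the lowest window lay on chromosome 18 from 12020648 to 31171305 in hg18 with a median of -0.86. Chance placing of changed genes is argued against (permutation p = 0.001, the smallest that 1000 shuffles can give), and a trend with signal level and gene density is too, though narrowly, since the median stayed at -0.71 with density included. With the window chosen on every other gene, 80% of the 25 genes left out of that choice lay below the genome-wide level, exactly the bound set for a difference in DNA copy number, but shared regulation of neighbours would give the same, no DNA was measured and base composition was not tested, so copy number stays open as a hypothesis (a first test on all genes of the window was dropped, since the choice of the window fixed its outcome). The shift was not confined to the window, with a median of -0.46 over the 40 genes before it and -0.16 over the 93 after it. Another 8 windows, on chromosomes 1, 2, 5, 6, 10 and X, were lower and 6 windows higher than 99% of shuffles gave. The highest lay on chromosome 8 from 144462950 to 145917838 at 0.80. The window on chromosome X, from 100555342 to 110890494, spans the 13 BEX and TCEAL genes described above, of which 11 were lower, so these are not separate observations.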
